A study of Homo sapiens with 8 samples.

How the data were processed

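Messenger RNA was profiled in 8 libraries of Ishikawa cells, a human endometrial cancer line, in 4 groups of 2. Per the labels, the cells stably expressed SID4x-dCas9-KRAB, a nuclease-dead Cas9 joined to transcriptional repressor domains. They were kept in estrogen-depleted medium for 5 to 7 days before guide RNA (gRNA) transfection. About 72 h after transfection, cells received 10 nM estradiol (E2) for 8 h or were left without it. RNA was taken by direct lysis in a buffer with 1% beta-mercaptoethanol, and 100 ng per sample entered a stranded poly(A) mRNA kit, per the labels' protocols. Nothing in the labels states that the 2 replicates of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical only.

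The deposited values were raw read counts per gene symbol, 1 table per library. Per the submitters' processing notes, reads were aligned with HISAT2, counted with HTSeq, and referred to the hg19 genome. The versions, the gene annotation and the strand setting of the counting are not given in the sources used here, so genes that overlap on opposite strands may share reads. The tables held 26364 genes, of which 5710 had no read in any library, and 5 closing summary categories that name no gene. These categories were kept out of library sizes and tests. They took 37.7% to 43.6% of all counted entries per library, mostly alignments that were not unique (22.0% to 30.2%) and reads over no annotated feature (11.6% to 14.3%). Ambiguous reads took 1.40% to 1.82%. Reads shared by near-identical genes can be lost or split by such counting, so values of multigene families, such as histones, ribosomal proteins and other genes with near-identical copies, are uncertain whether or not they are marked where they appear. No coordinates are given, because the reference at hand was of another build (GRCh38).

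Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filter on the 4 groups, which left 15546, and library sizes were scaled with TMM factors (0.921 to 1.02). All 8 libraries entered 1 fit with a coefficient per group, because 2 libraries per group leave only 4 residual degrees of freedom. Differences were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes, at an adjusted p under 0.05. Every adjusted p of a gene comes from that test unless another tool is named. Log2 fold changes are given ± SE, where the SE is the fold change divided by the root of the F statistic, and levels are given as CPM, scaled to library sizes adjusted by the TMM factors, as mean ± SD with n = 2. Only for IL1RN, which was not in the fit, and for the floors are CPM relative to the unadjusted gene reads of a library. The floors, and the exact test on pooled reads, cover counting error only, since the libraries carry no molecular identifiers. Bootstrap intervals of a median were drawn over the genes of a list, and cover the spread between its members, not that between libraries. Replicates of each group differed by more than sampling noise (chi-square per gene of 10.3 to 59.9), so none was a second copy of another. The floor of a library with no read for a gene was set at 3 reads.

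The comparisons were the E2 effect within each gRNA pool, the Enhancer-i effect without and with E2, the average of each pair, and the difference between the E2 effects of the pools. The averaged E2 effect selected estrogen-responsive genes without favouring either pool, and fry from limma 3.58.1 tested whether these genes moved, on balance, one way in the difference. The tests, the alternatives, 21 gene lists and the rule for naming genes were fixed before the data were examined, except for the additions named as such.

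The lists were candidate genes near the targeted sites, classical estrogen targets, endometrial epithelial products, epithelial identity genes, receptors and cofactors, S-phase genes, mitosis genes, ribosome biogenesis genes, interferon-stimulated genes, NF-kB inflammation genes, p53 targets, stress-response genes, cholesterol synthesis genes, hypoxia and glycolysis genes, immediate early genes, cytokine feedback genes, stromal, leukocyte and endothelial markers, replication-dependent histones and ribosomal proteins. The labels do not name the 10 targeted sites. The 7 site candidates, among them CISH, MMP17, FHL2, G0S2, PEG10 and CXCR4, were recalled as genes near estrogen receptor sites studied by the same laboratory in this line. Whether each was targeted is not known here. The list may rest on results of such experiments, so tests adjusted over it alone may not be those of an independently fixed set. Values of 1 candidate and of 1 cofactor gene are not reported here by name, but both genes stayed in every test. Lists were compared with all other genes by camera from limma, with a preset correlation of 0.01 and a prior count of 3, adjusted over the lists, and again with an estimated correlation. A list's adjusted p is camera's unless stated. Counts of list members are given over all genes and adjusted over the list alone.

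The named genes were, per comparison, those with adjusted p under 0.05, both libraries of 1 group above both of the other and a mean log2 CPM of at least 1, taking the 10 largest and 10 smallest log2 fold changes. IL1RN, ESR1, PGR, GREB1 and the other site candidates were named whatever their values, as were up to 4 members of each described list with the smallest p. The differences between E2 effects followed the same rule without the separation of libraries.

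Alternatives were RLE scaling, no filter on low counts, the replicate number as a block, DESeq2 1.42.0, limma-voom, a test against a 1.2-fold change, only the 2 groups compared, other selections of the responsive genes, and leaving out each library in turn. Robust dispersions and voom with sample quality weights were added after the data were seen, because 1 library stood apart. Leaving out a library leaves its group with 1 sample, which is then assumed to vary like the other groups. The fits were tested on simulated counts drawn from the real means and library sizes over 15546 genes, with 100 genes changed 2-fold and 100 changed 4-fold. For E2 in control gRNA cells 73 and 97 of these were recovered, with 13 false calls. For Enhancer-i with E2 the numbers were 70 and 99, with 11 false calls, and for the averaged E2 effect 87 and 100, with 19. For the difference of E2 effects only 14 of the 2-fold changes and 91 of the 4-fold changes were recovered, with 6 false calls. The changed genes were drawn from those with an average log2 CPM above 1. Every simulated library followed the same spread per gene, so none stood apart as 1 real library did. The recoveries therefore do not cover that case, which bears on every comparison with the Enhancer-i group with E2.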

Results

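RNA sequencing was used to follow how Enhancer interference (Enhancer-i), the recruitment of a repressor to enhancers by gRNAs, altered the transcriptome of Ishikawa cells before and after estrogen. Enhancer-i cells received a pool of 42 gRNAs directed at 10 sites bound by estrogen receptor α, and control cells a pool of 4 gRNAs directed at the promoter of IL1RN. Each pool was profiled without E2 and after 8 h of 10 nM E2, with 2 libraries per group. Reads assigned to genes came to 21845032 and 25439966 in control cells without E2 (replicates 1 and 2), and to 25440815 and 14626034 in control cells with E2. Enhancer-i cells gave 21641724 and 23260064 without E2, and 26661954 and 7551651 with E2.

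IL1RN, which encodes the interleukin-1 receptor antagonist and whose promoter the control gRNAs targeted, was close to undetected in every library. Control cells held 3 and 0 reads without E2 and 0 and 0 with E2, in replicate order. Enhancer-i cells held 3 and 8 reads without E2 and 6 and 2 with E2. In CPM this was 0.137 and 0 and then 0 and 0 in control cells, where a count of 0 allowed up to 0.118 CPM in control replicate 2 without E2, and up to 0.118 and 0.205 CPM in the control replicates with E2. Enhancer-i libraries lay at 0.139 and 0.344 CPM without E2 and at 0.225 and 0.265 CPM with E2. Summed over libraries, 3 of 87351847 gene reads in control cells and 19 of 79115393 in Enhancer-i cells came from IL1RN (exact two-sided binomial p = 0.000331). That test compares the reads of these libraries, not the conditions, and the gene was too low to enter the test across genes.

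Enhancer-i replicate 2 with E2 stood apart from the other 7 libraries. It scored 89.4 on the first principal component, which held 42.8% of the variance, while the other libraries lay between −16.1 and −5.7. Across genes, which are not independent replicates, it correlated with its replicate at r = 0.959, against 0.984 to 0.985 in the other groups. It detected 16488 genes, against 17629 to 18451 elsewhere, and RNA45S5, the ribosomal RNA precursor, took 3.75% of its gene reads against 1.18% to 2.54%. Genes of at least 10 CPM differed between its group's replicates by a root-mean-square of 0.508 on the log2 scale, against 0.166, 0.179 and 0.227 in the control group without E2, the control group with E2 and Enhancer-i cells without E2. Of 23 genes that differed over 16-fold between replicates with at least 50 reads, 15 did so in this group. This library enters the Enhancer-i group with E2 and, through the shared spread estimate, every test.

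In control gRNA cells, E2 raised 25 genes, among them 16-fold increases that were far larger than the spread between replicates. DHRS3, a retinaldehyde reductase, rose 16.5-fold (log2 fold change 4.04 ± 0.36, adjusted p = 0.00211), from 0.762 ± 0.259 to 12.5 ± 1.89 CPM (SD, n = 2). MMP17, a membrane-anchored matrix metalloproteinase, rose 16.1-fold (4.01 ± 0.26, adjusted p = 0.000324), from 1.15 ± 0.287 to 18.7 ± 0.395 CPM. The transcriptional regulator MN1 rose 8.59-fold (3.10 ± 0.34, adjusted p = 0.00901). ANO1, a calcium-activated chloride channel, rose 4.94-fold, and the carbonic anhydrase CA12 rose 4.49-fold. The transcription factor HES2 went from 33.3 ± 0.747 to 146 ± 3.17 CPM, 4.38-fold (2.13 ± 0.13, adjusted p = 0.000324). DEPTOR, an inhibitor of the mTOR kinase, rose 4.26-fold and the prostaglandin transporter SLCO2A1 4.01-fold. CACNA1I, a calcium channel subunit, and PLAT, the tissue plasminogen activator, completed the 10 largest increases among passing genes with a mean log2 CPM of at least 1 (PGR, below that level, follows), with log2 fold changes of 2.51 ± 0.28 and 2.27 ± 0.30.

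**Figure D1:**
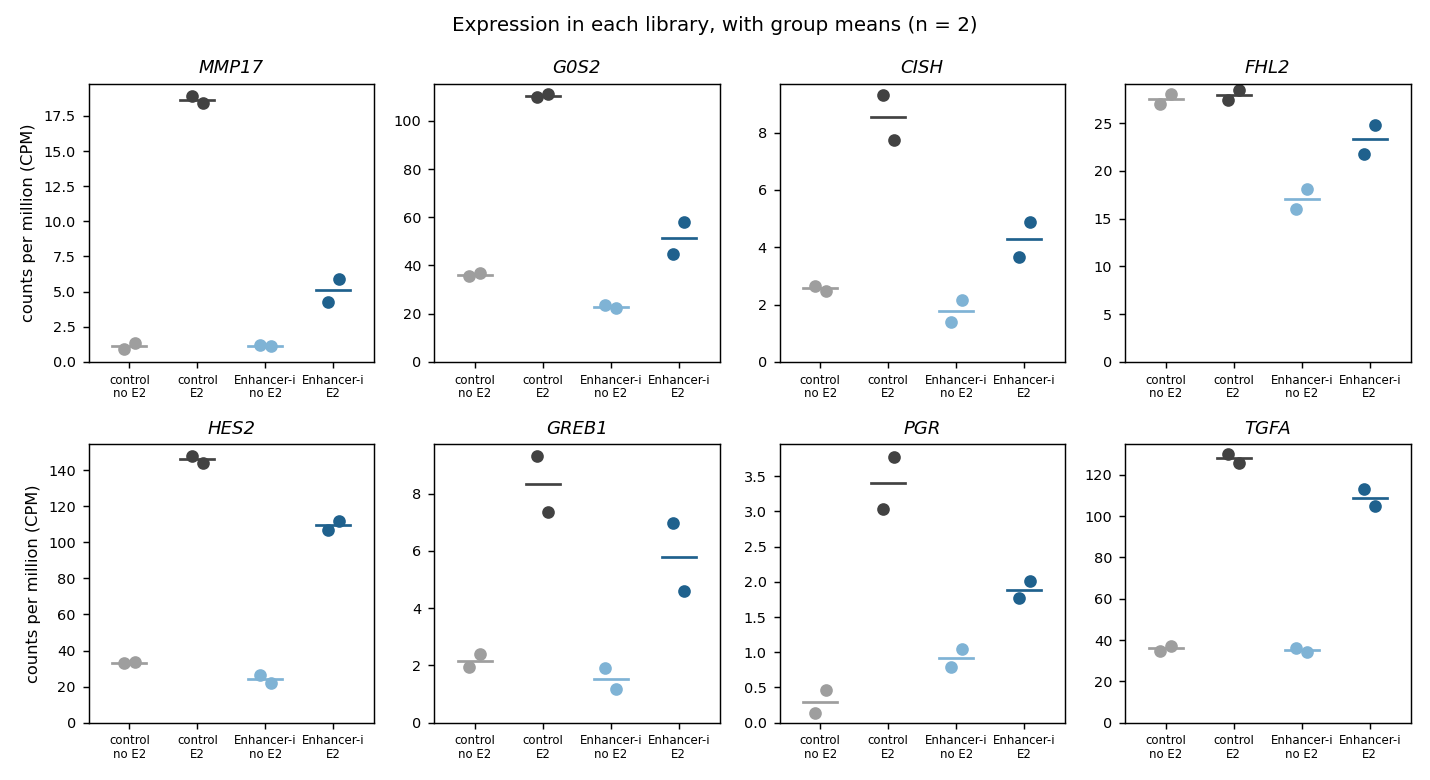
Each point is the CPM of 1 library for 1 of 8 genes in the 4 groups (control and Enhancer-i gRNAs, without and with E2), and the short lines are the means of 2 libraries, on axes that start at 0. MMP17 lay at 18.7 ± 0.395 CPM in control cells with E2 and at 5.09 ± 1.14 CPM in Enhancer-i cells with E2.

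Classical estrogen targets rose together in control cells (adjusted p = 2.48e-12, and adjusted p = 0.0257 with an estimated correlation). Of 22 tested members, 4 rose over all genes and 8 adjusted over the list alone, 19 lay above 0, and none fell. The growth factor TGFA rose by 1.83 ± 0.12 (adjusted p = 0.000324), from 36.1 ± 1.68 to 128 ± 2.77 CPM. MYC, the growth-promoting transcription factor, rose by 1.01 ± 0.13 (adjusted p = 0.0174). PGR, the progesterone receptor, rose by 3.44 ± 0.52 (adjusted p = 0.0496) from 0.299 ± 0.232 to 3.40 ± 0.515 CPM. That value ranged from 2.85 to 4.59 when single libraries were left out, and did not pass without any 1 of the 6 libraries outside the Enhancer-i group with E2. GREB1, a coactivator of the estrogen receptor, gave 1.94 ± 0.32 (adjusted p = 0.0799). The receptor gene ESR1 itself gave −0.32 ± 0.21 (adjusted p = 0.865).

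Of the 7 site candidates, MMP17 and G0S2, an inhibitor of adipose triglyceride lipase, rose over all genes, and 4 rose adjusted over the list alone. G0S2 rose 3.05-fold (1.61 ± 0.15, adjusted p = 0.00224). CISH, a suppressor of cytokine signalling, gave 1.74 ± 0.28 (adjusted p = 0.0799). PEG10, FHL2 and CXCR4 gave 0.45 ± 0.20, 0.02 ± 0.14 and −0.10 ± 0.26, and the last 2 changed sign when single libraries were left out. The list's call (adjusted p = 4.39e-08) was lost with an estimated correlation (adjusted p = 0.075).

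Ribosome biogenesis genes lay slightly higher with E2, with 19 of 20 members above 0 and a median of 0.26 (adjusted p = 1.55e-05, and adjusted p = 0.253 with an estimated correlation). Its leading members were POLR1B, a subunit of RNA polymerase I (0.40 ± 0.15), and the nucleolar GTPase GNL3 (0.33 ± 0.14), and none passed by itself, over all genes or adjusted over the list alone. Cytokine feedback genes were also higher (adjusted p = 0.0433, and adjusted p = 0.367 with an estimated correlation). CISH and the kinase PIM1 (0.72 ± 0.15) rose adjusted over the list alone, although the median over the list was only 0.13. That call was lost without any 1 of 6 libraries, the exceptions being control replicate 2 and Enhancer-i replicate 1, both without E2 (adjusted p up to 0.284 without control replicate 1 without E2). It was also lost with no filter on low counts (adjusted p = 0.0696).

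Interferon-stimulated genes lay lower with E2 in control cells, with 12 of 14 below 0 and a median of −0.39 (adjusted p = 0.0135, and adjusted p = 0.313 with an estimated correlation). None passed singly. Their leading members were the transcription factor IRF7 (−0.45 ± 0.17) and the antiviral GTPase MX1 (−1.26 ± 0.58), and the call was lost without control replicate 1 with E2 (adjusted p = 0.0634) and with no filter on low counts (adjusted p = 0.229). Of 18 epithelial identity genes, 14 lay below 0 (median −0.17, adjusted p = 0.0135, and adjusted p = 0.426 with an estimated correlation). The lineage factor PAX8 fell adjusted over the list alone (−0.59 ± 0.12, adjusted p = 0.0103 in that test). Leaving out control replicate 1 with or without E2 ended that call (adjusted p = 0.0897 and 0.123). Replication-dependent histones lay lower in 11 of 12 members (median −0.28, adjusted p = 0.0433, and adjusted p = 0.488 with an estimated correlation), with HIST1H2AC at −0.35 and HIST1H4H at −0.50, although the similar copies of this family may share reads. The histone call was lost without control replicate 1 with E2 (adjusted p = 0.452), without control replicate 1 without E2 (adjusted p = 0.284), without Enhancer-i replicate 2 without E2 (adjusted p = 0.0502) and with no filter on low counts (adjusted p = 0.148).

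The other lists did not pass as groups in control cells. Among endometrial epithelial products (adjusted p = 0.202) the placental-type alkaline phosphatases ALPPL2 and ALPP rose adjusted over the list alone (2.37 ± 0.43 and 3.0 ± 0.76), but as near-identical paralogs they may share reads. Among p53 targets (adjusted p = 0.419) the kinase PLK2 fell adjusted over the list alone (−0.63 ± 0.11). Among stromal markers (adjusted p = 0.119) COL1A1, COL3A1 and ACTA2 fell and THY1 rose adjusted over the list alone, with log2 fold changes of −0.56, −0.47, −0.43 and 1.61. Adjusted p-values were 0.621 for S-phase genes, 0.825 for mitosis genes, 0.113 for NF-kB inflammation genes, 0.419 for cholesterol synthesis genes and 0.784 for hypoxia and glycolysis genes. They were 0.346 for immediate early genes, 0.054 for receptors and cofactors, 0.65 for leukocyte markers and 0.0586 for endothelial markers. Ribosomal proteins (adjusted p = 0.621) and stress-response genes (adjusted p = 0.727) did not pass either, and for the stress-response genes the median of 0.04 and the downward test differed in sign.

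By edgeR's quasi-likelihood test 1 gene fell over all genes in control cells, the long noncoding RNA LINC01001, from 3.33 ± 0.566 to 0.231 ± 0.0543 CPM (−3.86 ± 0.50, adjusted p = 0.0201). It lies under the expression minimum and was chosen after its values were seen. In all, 26 of 15546 genes passed edgeR's quasi-likelihood test, against 77 with DESeq2 (53 higher and 24 lower) and 29 with limma-voom (28 higher and 1 lower). It was 139 with no filter on low counts, 461 with voom and quality weights, and 653 with only the 2 groups compared. At an unadjusted p under 0.05, 419 lay higher and 536 lower. The count was 6 to 15 without any 1 of the 6 libraries outside the Enhancer-i group with E2, and it was 252 and 276 without replicate 1 and replicate 2 of that group, where all 26 genes were among those passing. GREB1 and CISH passed without either of these (adjusted p = 0.00212 and 0.00277 without replicate 1) and with DESeq2 (adjusted p = 0.000194 and 0.000865).

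In Enhancer-i cells, E2 raised 19 genes and lowered none by edgeR's quasi-likelihood test, while DESeq2 called 12 lower. DHRS3 rose 11.3-fold (3.50 ± 0.35, adjusted p = 0.0067), from 1.06 ± 0.402 to 12.3 ± 3.2 CPM (SD, n = 2), and CA12 rose 6.43-fold (2.69 ± 0.28, adjusted p = 0.0095). HES2, DEPTOR and ANO1 rose 4.54-fold, 4.38-fold and 4.30-fold, each with adjusted p = 0.000615. MMP17 rose 4.22-fold (2.08 ± 0.28, adjusted p = 0.0348), from 1.16 ± 0.0595 to 5.09 ± 1.14 CPM. The phosphodiesterase gene GDPD5, the corepressors CBFA2T3 and HR, and the neurotrophic factor NRTN also rose, by 2.22 ± 0.26, 2.00 ± 0.22, 1.72 ± 0.20 and 1.71 ± 0.22 on the log2 scale.

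All 7 site candidates lay above 0 in Enhancer-i cells, PEG10 only at 0.10 and at −0.28 without Enhancer-i replicate 1 with E2 (list adjusted p = 4.41e-08, and adjusted p = 0.0701 with an estimated correlation). Over all genes 3 rose, among them MMP17 and G0S2 (1.16 ± 0.15, adjusted p = 0.0301), and 5 rose adjusted over the list alone. CISH gave 1.22 ± 0.31 (adjusted p = 0.517) and FHL2 0.44 ± 0.14 (adjusted p = 0.72). Of 22 classical estrogen targets, 3 rose over all genes and 6 adjusted over the list alone (list adjusted p = 1.42e-07, and adjusted p = 0.0701 with an estimated correlation), among them TGFA (1.63 ± 0.12) and MYC (0.89 ± 0.13). GREB1, PGR and ESR1 gave 1.96 ± 0.34, 1.02 ± 0.48 and −0.64 ± 0.21 and did not pass (adjusted p = 0.125, 0.72 and 0.72), although DESeq2 called GREB1 (adjusted p = 0.000812). Without Enhancer-i replicate 1 with E2, only the library that stood apart represented the group, and GREB1, CISH, FHL2 and ESR1 gave 1.58, 1.45, 0.53 and −1.06. ESR1 ranged from −1.06 to −0.35 as single libraries were left out. Without replicate 2 of that group GREB1 gave 2.20.

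Ribosome biogenesis genes lay above 0 in 18 of 20 members in Enhancer-i cells too (median 0.29, adjusted p = 3.26e-06, and adjusted p = 0.216 with an estimated correlation), led by the pseudouridine synthase DKC1 (0.41 ± 0.12) and NOP16 (0.54 ± 0.17). Endometrial epithelial products passed (adjusted p = 0.026, and adjusted p = 0.256 with an estimated correlation), where ALPP (3.71 ± 0.79) and ALPPL2 (1.90 ± 0.46) rose adjusted over the list alone. Their call was lost without either Enhancer-i library with E2 (adjusted p = 0.0678 and 0.411 without replicates 1 and 2) and with no filter on low counts (adjusted p = 0.173). All 23 ribosomal protein genes lay above 0 (median 0.42, adjusted p = 1.28e-06, and adjusted p = 0.876 with an estimated correlation), with none passing singly. Without Enhancer-i replicate 2 with E2, the library that stood apart, their median was −0.01 (adjusted p = 0.769).

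The 19 genes of edgeR's quasi-likelihood test compared with 60 by DESeq2, of which 12 were lower, 18 by limma-voom, 183 with no filter on low counts, 8 with only the 2 groups compared and 8 with voom and quality weights, and 380 genes lay lower at an unadjusted p under 0.05. The number was 1 to 14 without any 1 of the other 6 libraries, and 4203 and 54 without Enhancer-i replicates 1 and 2 with E2. Of the 25 genes that rose in control cells and the 19 in Enhancer-i cells, 18 were the same, where independent lists would share 0.031 (Fisher's exact two-sided p = 2.1e-53). The 2 comparisons share no libraries, but both use the spread per gene estimated from all 8. Genes are also not independent replicates, so that p-value is not one of independent lists. CACNA1I, MN1, MUC5B, PGR, PLAT, SLCO2A1 and SLIT3 passed in control cells alone and 1 gene in Enhancer-i cells alone, but all 25 lay above 0 in Enhancer-i cells and all 19 in control cells.

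Averaged over both pools, E2 raised 61 genes and lowered 24. HES2, ANO1, DEPTOR and TGFA rose by 2.16 ± 0.09, 2.20 ± 0.10, 2.11 ± 0.10 and 1.73 ± 0.08 (each adjusted p = 2.03e-05). GREB1 (1.95 ± 0.23, adjusted p = 0.00701), CISH (1.48 ± 0.21, adjusted p = 0.0191) and PGR (2.23 ± 0.35, adjusted p = 0.0327) rose as well. FHL2 gave 0.23 ± 0.10 (adjusted p = 0.571). Among the genes that fell, chosen for naming after their values were seen, were the basal keratins KRT5 (−0.63, adjusted p = 0.0215) and KRT17 (−0.57, adjusted p = 0.0406). The multidrug transporter ABCC3 (−0.82, adjusted p = 0.0101), the Notch ligand JAG1 (−0.75, adjusted p = 0.0359) and the growth factor binding protein IGFBP3 (−0.61, adjusted p = 0.0208) also fell. POTEE gave the lowest value, −5.38, but belongs to a family of near-identical copies, with 30 and 944 reads in control cells and 2648 and 2343 in Enhancer-i cells without E2 and at most 45 in any library with E2, and is uncertain. The 85 genes became 175 with DESeq2, 345 with no filter on low counts and 41 against a 1.2-fold change, and lay between 24 and 34 without any 1 of the libraries outside the Enhancer-i group with E2. They became 3093 and 362 without replicates 1 and 2 of that group.

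**Figure D2:**
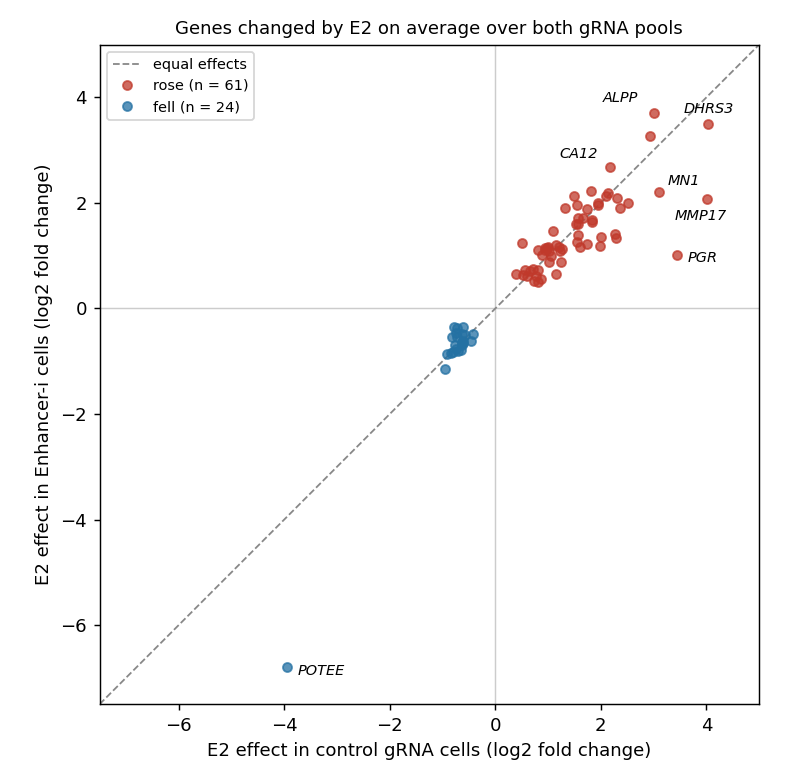
Each point is a gene whose averaged E2 effect passed, placed by its log2 fold change with E2 in control cells (horizontal) and in Enhancer-i cells (vertical), in red for the 61 that rose and blue for the 24 that fell, with a dashed line of equal effects. MMP17 lay below the line, at 4.01 in control and 2.08 in Enhancer-i cells.

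Without E2, FHL2, a LIM domain coactivator, and G0S2 lay lower in Enhancer-i cells in the test of the 7 site candidates alone. That list may not be an independently fixed set. FHL2 lay at 17.1 ± 1.53 CPM (SD, n = 2) in Enhancer-i cells and 27.5 ± 0.67 CPM in control cells, 1.61-fold lower (−0.69 ± 0.14, adjusted p = 0.00439 over the list alone). G0S2 lay at 22.8 ± 0.944 against 36.3 ± 0.722 CPM, 1.59-fold lower (−0.67 ± 0.15, adjusted p = 0.00439 over the list alone). Over all genes neither passed (both adjusted p = 0.857), although without Enhancer-i replicates 1 and 2 with E2, each left out alone, FHL2 (adjusted p = 0.0409 and 0.0285) and G0S2 (adjusted p = 0.0159 and 0.00952) did. MMP17, which was near 1.15 CPM in both pools without E2, gave 0.01 ± 0.30, and CISH, PEG10 and CXCR4 gave −0.52 ± 0.30, −0.05 and −0.11. MMP17 and PEG10 changed sign when single libraries were left out. The candidates as a list were lower, 6 of 7 below 0 (adjusted p = 0.0134, and adjusted p = 0.612 with an estimated correlation). That call was lost without control replicate 2 without E2 (adjusted p = 0.113). PGR, GREB1 and ESR1 gave 1.56 ± 0.55, −0.50 ± 0.34 and −0.15 ± 0.21, and none passed. They ranged from 0.97 to 2.71, −0.89 to −0.19 and −0.22 to −0.08 as single libraries were left out.

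Stress-response genes, which serve protein folding in the endoplasmic reticulum and amino acid supply, were higher in Enhancer-i cells without E2, 16 of 20 above 0 with a median of 0.23 (adjusted p = 0.00371). That call was lost with an estimated correlation (adjusted p = 0.612) and without Enhancer-i replicate 2 without E2 (adjusted p = 0.0659). The cochaperone DNAJB9 (0.56 ± 0.15), HERPUD1 (0.44 ± 0.12) and the chaperone HSPA5 (0.41 ± 0.13) were higher and DDIT4 lower (−0.48 ± 0.16), none passing singly, over all genes or adjusted over the list alone. Immediate early genes were higher (median 0.10, 12 of 18 above 0, adjusted p = 0.0289, and adjusted p = 0.612 with an estimated correlation). CTGF, a secreted matricellular protein, rose adjusted over the list alone (0.58 ± 0.14, adjusted p = 0.04 in that test). This list's call was lost without control replicate 1 without E2 (adjusted p = 0.157), without Enhancer-i replicate 2 without E2 (adjusted p = 0.441), and without either Enhancer-i library with E2 (adjusted p = 0.131 and 0.142 without replicates 1 and 2).

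Epithelial identity genes were lower in Enhancer-i cells without E2, 15 of 18 below 0 with a median of −0.15 (adjusted p = 0.00904, and adjusted p = 0.612 with an estimated correlation), led by the transcription factor ELF3 (−0.40 ± 0.12). None passed singly, and the list did not pass without replicate 1 of control or of Enhancer-i cells without E2 (adjusted p = 0.108 and 0.109). Interferon-stimulated genes were lower in 12 of 14 members (median −0.21, adjusted p = 0.0326, and adjusted p = 0.612 with an estimated correlation), with IFITM1 at −1.06 ± 0.36. Their call was lost without either control library without E2 (adjusted p = 0.127 and 0.0619 without replicates 1 and 2) and without Enhancer-i replicate 1 without E2 (adjusted p = 0.388), as well as with no filter on low counts, where 19 members were tested (adjusted p = 0.161).

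No gene passed over all 15546 genes by edgeR's quasi-likelihood test, where 401 lay higher and 465 lower at an unadjusted p under 0.05 and the smallest adjusted p was 0.857. EdgeR called 20 with no filter on low counts and 52 with only the 2 groups compared. Limma-voom called 0 genes, or 1 with quality weights, and DESeq2 4, chosen for naming after their values were seen. These were the desaturase FADS2 (−0.71, adjusted p = 0.0131), the actin-bundling protein ESPN (−0.62, adjusted p = 0.0438), LINC01001 (−3.13, adjusted p = 0.0438) and the cytochrome CYP1B1 (0.79, adjusted p = 0.0438). Without Enhancer-i replicates 1 and 2 with E2, edgeR called 53 and 69 genes, although neither library is part of this comparison.

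With E2, MMP17 and G0S2 were lower in Enhancer-i than in control cells, and ranked first and second of all genes by p. MMP17 reached 5.09 ± 1.14 CPM (SD, n = 2) against 18.7 ± 0.395 CPM, 3.78-fold lower (−1.92 ± 0.24, adjusted p = 0.211 over all genes and 9.5e-05 over the list alone). G0S2 reached 51.4 ± 9.55 against 111 ± 0.118 CPM, 2.17-fold lower (−1.12 ± 0.15, adjusted p = 0.211 over all genes). CISH lay at 4.27 ± 0.873 against 8.53 ± 1.11 CPM (−1.04 ± 0.28, adjusted p = 0.804 over all genes and 0.0119 over the list alone). These 3 of the 7 site candidates passed adjusted over the list alone and 0 over all genes. FHL2, PEG10 and CXCR4 gave −0.27 ± 0.14, −0.39 ± 0.20 and 0.33 ± 0.27. PEG10 was −0.78 without Enhancer-i replicate 1 with E2, where only the library that stood apart represented the group, and −0.10 without replicate 2. CXCR4 was 0.03 and 0.66 without control replicates 1 and 2 with E2. The candidates passed as a list (adjusted p = 0.00186, and adjusted p = 0.509 with an estimated correlation), but not without Enhancer-i replicate 1 with E2 (adjusted p = 0.27). GREB1, PGR and ESR1 gave −0.48 ± 0.30, −0.86 ± 0.45 and −0.47 ± 0.21, none of which passed. GREB1 ranged from −0.87 to −0.26 as single libraries were left out. ESR1 was −0.89 without Enhancer-i replicate 1 with E2 and −0.19 without replicate 2.

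Stress-response genes were higher in Enhancer-i cells with E2, 16 of 20 above 0 with a median of 0.35 (adjusted p = 9.05e-06), and 8 rose adjusted over the list alone and 0 over all genes. The call was lost with an estimated correlation (adjusted p = 0.526). HSPA5 (0.53 ± 0.13), HERPUD1 (0.48 ± 0.12), the pseudokinase TRIB3 (0.50 ± 0.12) and the transcription factor DDIT3 (0.72 ± 0.20) led it, with HSPA5 at 1930 ± 248 against 1340 ± 10.4 CPM. Without replicate 2, the library that stood apart, the list's median was 0.11 (adjusted p = 0.000349). Immediate early genes were higher in 14 of 18 members (median 0.21, adjusted p = 0.000598, and adjusted p = 0.509 with an estimated correlation). CTGF (0.71 ± 0.14), CYR61, a related matricellular protein (0.58 ± 0.12), and the transcription factor FOSL1 (0.67 ± 0.17) rose adjusted over the list alone. The median was 0.10 without replicate 2 (adjusted p = 0.00483), and the call was lost without replicate 1 of the same group (adjusted p = 0.0579).

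Receptors and cofactors lay below 0 in 19 of 19 members with E2 (median −0.33, adjusted p = 1.17e-05, and adjusted p = 0.585 with an estimated correlation), among them the pioneer factor FOXA1 (−0.32 ± 0.14) and ESR1. Ribosomal proteins lay above 0 in 23 of 23 (median 0.37, adjusted p = 9.05e-06, and adjusted p = 0.664 with an estimated correlation), with RPS12 at 0.48, a gene family whose copies may share reads. Neither list had a member that passed, over all genes or adjusted over the list alone. Both calls were lost without the library that stood apart, with medians of −0.06 (adjusted p = 0.196) and −0.05 (adjusted p = 0.458). Interferon-stimulated genes did not pass, and their median of −0.01 and mean of 0.15 differed in sign.

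**Figure D3:**
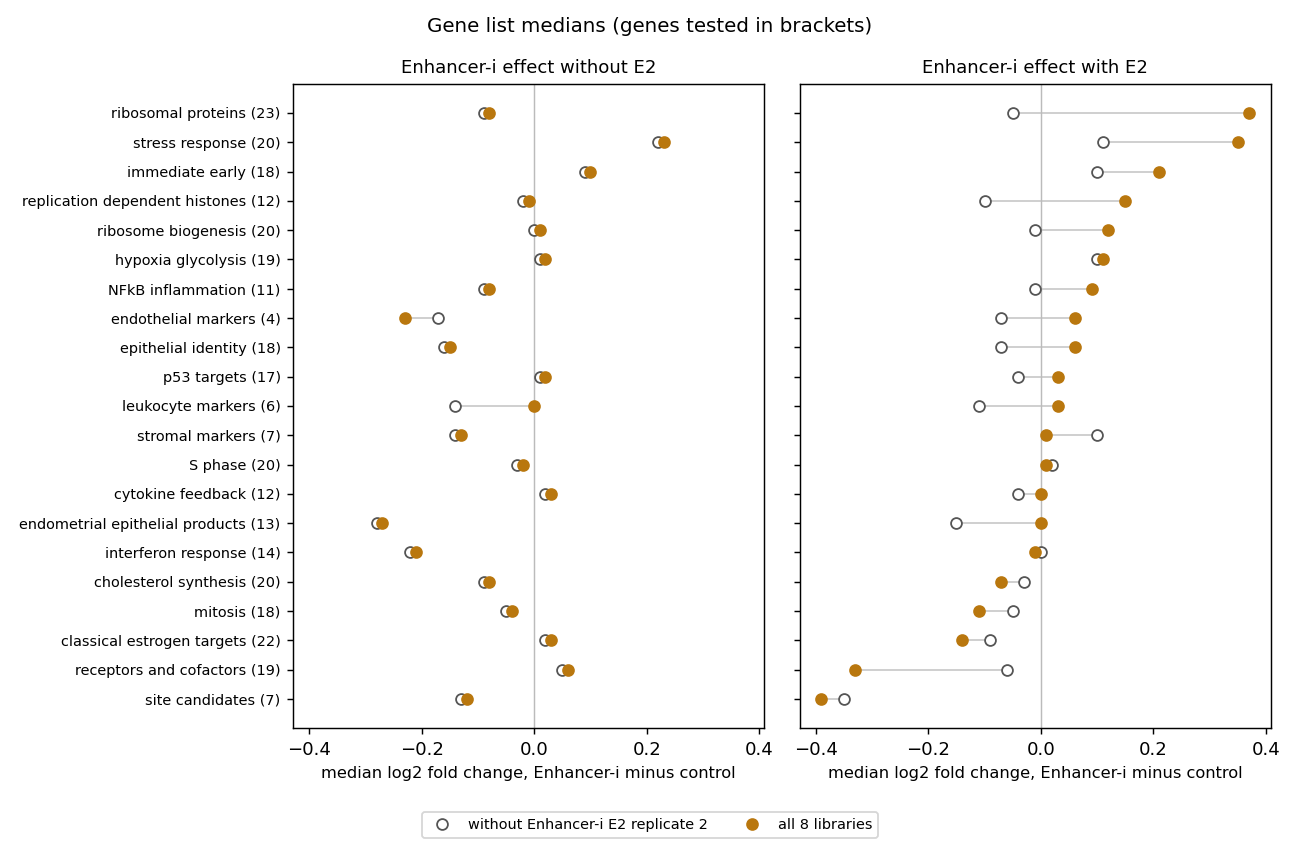
Medians of the Enhancer-i log2 fold change over each of 21 gene lists, without E2 (left) and with E2 (right), from all 8 libraries (filled) and without Enhancer-i replicate 2 with E2 (open). The stress-response median with E2 moved from 0.35 to 0.11 without that library, and the ribosomal protein median from 0.37 to −0.05.

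EdgeR's quasi-likelihood test called 0 genes with E2 over all genes (smallest adjusted p = 0.211), with 365 higher and 298 lower at an unadjusted p under 0.05. DESeq2 called 2, MMP17 (adjusted p = 1.91e-05) and G0S2 (adjusted p = 9.07e-06), and limma-voom called 1, MMP17 (adjusted p = 0.0471), while edgeR called 70 with no filter on low counts. Without Enhancer-i replicate 2 with E2, edgeR called 7, which were MMP17 (−2.12 ± 0.26, adjusted p = 0.00339), G0S2 (−1.31 ± 0.12, adjusted p = 0.000212) and 5 others. Of these 5, 3 were among the genes that differed over 16-fold between the replicates of this group, so their calls depend on which library was kept. Without replicate 1 of that group, only the library that stood apart represented it, and 4010 genes were called.

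Averaged over both E2 states, G0S2 had the smallest adjusted p of the Enhancer-i effect, −0.89 ± 0.10 (adjusted p = 0.157). FADS2 (−0.59 ± 0.08, adjusted p = 0.234), ESPN (−0.57 ± 0.08) and CTGF (0.64 ± 0.10, adjusted p = 0.295), chosen after their values were seen, did not pass edgeR's quasi-likelihood test either. DESeq2 called these 4 genes on the same libraries, G0S2 with adjusted p = 3.12e-08, FADS2 and ESPN each with adjusted p = 2.8e-05 and CTGF with adjusted p = 0.000126. EdgeR called 0 genes, with 501 higher and 577 lower at an unadjusted p under 0.05, where DESeq2 called 32, limma-voom 0, or 4 with quality weights, and edgeR with no filter on low counts 102. Without Enhancer-i replicates 1 and 2 with E2, edgeR called 2615 and 117 genes.

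The difference between the E2 effects of the pools asks whether Enhancer-i altered the estrogen response itself. MMP17 responded less in Enhancer-i cells, by −1.93 ± 0.38 on the log2 scale, which passed adjusted over the list of site candidates alone (adjusted p = 0.00467) and over the 61 genes that rose with E2 (adjusted p = 0.0407), but not over all genes (adjusted p = 0.848) or all 85 responsive genes (adjusted p = 0.0568). The value ranged from −2.22 to −1.67 when single libraries were left out, and over all genes it did not pass without Enhancer-i replicate 2 with E2, the library that stood apart (−2.12, adjusted p = 0.215) or with DESeq2 (adjusted p = 0.999). It passed with no filter on low counts (adjusted p = 0.0158), and without replicate 1 of that group (adjusted p = 0.0101), a fit in which that library alone stood for the group and 3223 genes passed. G0S2 (−0.45 ± 0.20), CISH (−0.52 ± 0.42), FHL2 (0.42 ± 0.20) and PGR (−2.41 ± 0.71) did not pass. Over the 61 risen genes the median difference was 0.02, with quartiles of −0.29 and 0.16 and a smaller response in Enhancer-i cells for 29. Over the 24 fallen genes it was 0.01. Fry's p-values were 0.187 and 0.772. The risen genes had median E2 effects of 1.52 in control and 1.25 in Enhancer-i cells.

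As groups, ribosomal proteins (23 of 23 above 0), epithelial identity genes (13 of 18) and interferon-stimulated genes (12 of 14) had a higher E2 effect in Enhancer-i cells (adjusted p = 4.82e-05, 0.0229 and 0.0445), and receptors and cofactors a lower one (16 of 19 below 0, adjusted p = 0.00197). Each call was lost with an estimated correlation (adjusted p = 0.686 for each). Each was also lost without Enhancer-i replicate 2 with E2 (adjusted p = 0.474, 0.222, 0.222 and 0.402 in the same order), and that of the interferon-stimulated genes also with no filter on low counts (adjusted p = 0.47). No single gene passed over all genes in edgeR's quasi-likelihood test, with 193 higher and 206 lower at an unadjusted p under 0.05. DESeq2 and limma-voom called 0, and edgeR called 35 genes with no filter on low counts, 3223 genes without replicate 1 and 1 gene, MXRA7, without replicate 2 of the Enhancer-i group with E2.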

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

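The tests of MMP17 and G0S2 without the deviating library, of a general loss of the estrogen response, and of the stress-response genes without that library were chosen only after the result was seen. Tests of the difference between the E2 effects of the pools singled out MMP17 and 4 gene lists. MMP17 responded less to E2 in Enhancer-i cells, with a difference of −1.93 on the log2 scale. It passed over the site candidates (adjusted p = 0.00467) and the 61 risen genes (adjusted p = 0.0407). It did not pass over all 85 responsive genes (adjusted p = 0.0568) or over all genes (adjusted p = 0.848). The calls of all 4 lists were lost with an estimated correlation (adjusted p = 0.686 for each). Ribosomal proteins had a median difference of 0.43, and this call was lost without Enhancer-i replicate 2 with E2 (adjusted p = 0.474). Receptors and cofactors had a median difference of −0.35, lost without the same library (adjusted p = 0.402). Interferon-stimulated genes had 0.38 and epithelial identity genes 0.28, each lost without that library (adjusted p = 0.222 for both). Leaving out any 1 of 4 further libraries (either control library with E2, control replicate 1 or Enhancer-i replicate 1 without E2) also ended both calls, with adjusted p up to 0.51 and 0.164, and for the interferon-stimulated genes so did leaving out Enhancer-i replicate 1 with E2 (adjusted p = 0.0697).

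Enhancer-i replicate 2 with E2 differed from its replicate 2.23 times as much, as a root-mean-square log2 difference, as the next most different pair. Its lower depth of 7551651 gene reads did not account for this, since the ratio was 2.05 after every library was thinned to that depth. A trend with GC content and transcript length held 38.7% of the squared difference in this pair and 36.4% in Enhancer-i cells without E2. The ratio was 2.02 once that trend was removed, but it could change little, since both pairs carried the trend. After thinning, removal took this pair from 0.511 to 0.399, which still exceeded the 0.19 to 0.198 left in the other pairs. So the trend accounted for a part only. Across genes, this pair's difference had a rank correlation of −0.65 with transcript length, against −0.32 to 0.22 in the other pairs. RNA45S5 took 3.75% of its gene reads, the highest share of the 8. Partial loss of RNA, unequal handling or a real difference between cultures may lie behind the remainder, and none of these was tested.

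MMP17 and G0S2 lay lower in Enhancer-i cells with E2, by a mean log2 fold change of −1.52. The deviating library alone did not produce this, because without it the mean was −1.71 and both genes passed over all genes (adjusted p = 0.00339 and 0.000212). The other 57 risen genes argued only against a generally smaller rise with E2. Their median difference of E2 effects was 0.02 (95% bootstrap interval −0.13 to 0.06). However, as single libraries were left out, the median over the risen genes of each fit ranged from −0.14 to 0.54. The 0.54 came without Enhancer-i replicate 1 with E2. That difference cannot show a lowering present in both E2 states. These 57 genes had median Enhancer-i effects of −0.22 without E2 and −0.21 with E2. A general lowering of estrogen-raised genes, though smaller than the mean of −1.52, therefore stays open as a part of the pattern. Silencing that spreads to neighbouring genes cannot be told apart from a local effect, since 16 neighbours of FHL2, G0S2, CISH and MMP17 (gene order from RefSeq genes of GRCh38.p14) had a median averaged Enhancer-i effect of −0.04, at percentile 9.93 of 10000 random sets matched on expression, while 1 of them, LAMB3 beside G0S2, chosen after its value was seen, gave −0.35 and passed over all genes without the deviating library (−0.36, adjusted p = 0.0185). A hypothesis is that gRNAs of the pool act on enhancers of these genes, which may be tested once the 10 sites are known, since the labels do not name them.

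Stress-response genes were higher in Enhancer-i cells, with medians of 0.23 without E2 and 0.35 with E2, calls that were lost with an estimated correlation (adjusted p = 0.612 and 0.526) and, without E2, also when Enhancer-i replicate 2 without E2 was left out (adjusted p = 0.0659). The deviating library cannot be told apart from the gRNA pool as a source of the second, because the median was 0.11 without it (95% bootstrap interval 0.07 to 0.33). In the comparison without E2, which does not contain that library, the median was 0.22 in a fit without it (0.05 to 0.30). Removing a GC and length trend moved the mean of both medians from 0.29 to 0.21 (0.07 to 0.43), an interval that covers both values, so a part played by that trend stays open. The pools also differed in their number of gRNAs (42 against 4), and whether that or the loss of enhancer function raised these genes was not tested.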

How the results depend on the processing

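The fits with robust dispersions and with quality weights were chosen only after the result was seen. With RLE scaling no count of genes changed. With no filter on low counts, genes changed by E2 came to 139 in control and 183 in Enhancer-i cells, those changed by Enhancer-i to 20 without and 70 with E2, the averaged effects to 345 (E2) and 102 (Enhancer-i) and the difference to 35. There the fallen genes' median difference was −0.01, and 4 lists were called for E2 in control cells. DESeq2 gave 77, 60, 4, 2, 175 and 32 for the first 6 counts, and limma-voom 1 gene for Enhancer-i with E2. Testing against a 1.2-fold change left 41 genes for the averaged E2 effect. Robust dispersions moved no count by over 1.5 times. Only the 2 groups compared gave 653, 8 and 52 for the first 3 counts. Quality weights gave 461, 8 and 1 (FADS2) for these and 4 for the averaged Enhancer-i effect (FADS2, ESPN, G0S2 and CTGF), genes chosen after their values were seen. These weights did not single out the library that stood apart. Enhancer-i replicates 1 and 2 with E2 were weighted 0.268 and 0.416, so the other replicate was lowered more. Weights were 0.949 and 0.945 in Enhancer-i cells without E2 and 1.72 to 1.84 in control cells. With an estimated correlation 1 list was called for E2 in control cells and 0 in every other comparison. Selecting risen genes by the control effect, which favours genes high there, gave a median difference of −0.16. Apart from these constructions the cause was not tested.

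Leaving out 1 library at a time moved the counts from 6 to 276 (E2 in control), 1 to 4203 (E2 in Enhancer-i), 0 to 69 and 0 to 4010 (Enhancer-i without and with E2), 24 to 3093 and 0 to 2615 (averages) and 0 to 3223 (difference). The highest came without Enhancer-i replicate 1 with E2, except 276 and 69, which came without replicate 2. Called lists ranged from 3 to 8 and 4 to 5 for E2, 2 to 5 and 3 to 5 for Enhancer-i, and 0 to 5 for the difference. Median differences ranged from −0.14 to 0.54 for risen and −0.67 to 0.16 for fallen genes, in the 3 fits with at least 3 of these. Signs changed for E2 effects of PEG10 in Enhancer-i cells (−0.28 to 0.41), and of CXCR4 (−0.43 to 0.20) and FHL2 (−0.01 to 0.05) in control cells. They changed for Enhancer-i effects of MMP17 (−0.21 to 0.30) and PEG10 (−0.11 to 0.02) without E2. Of the other values of single genes under all settings, 568 kept their direction and side of the threshold, 61 kept their direction but no longer passed and 35 newly passed. The shallowest library held 7551651 gene reads, which limits what can be shown for weakly expressed genes.

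The replicate numbers gave no clear pairing across the groups, as deviations correlated between −0.07 and 0.16, highest between the 2 groups with E2. These values cannot exclude pairing within those 2 groups. Replicate 1 of Enhancer-i and of control cells with E2 correlated with each other at r = 0.99. That was above the correlation of each with its own replicate (0.959 and 0.984). With the number as a block the counts were 26, 18, 0, 0, 64, 0 and 0, and the risen genes' median difference was −0.05. List calls lost with the block were cytokine feedback genes for E2 in control cells (adjusted p = 0.0521) and interferon-stimulated genes for the difference (adjusted p = 0.0516).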

Other observations

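The biology in this part, and its tests other than the splits into 4 and 4 libraries, were chosen only after the result was seen. In a fit without Enhancer-i replicate 2 with E2, the averaged Enhancer-i effect called 117 genes, 55 higher and 62 lower, with edgeR's quasi-likelihood test. Among those that fell were the desaturases FADS2 (−0.56, adjusted p = 0.00154) and SCD (−0.36, adjusted p = 0.0126), the transcription factor SREBF1 (−0.43, adjusted p = 0.00702) and the sodium channel subunit SCNN1A (−0.58, adjusted p = 0.00331). These were single genes picked from the 117, and no group of them was tested for enrichment. Among those that rose were the matricellular proteins CTGF (0.57, adjusted p = 0.00331) and CYR61 (0.46, adjusted p = 0.00455), ANKRD1 (0.40, adjusted p = 0.0126) and CYP1B1 (0.67, adjusted p = 0.00236). HSPA5 (0.40, adjusted p = 0.00352), HERPUD1 (0.41, adjusted p = 0.00702), DNAJB9 (0.46, adjusted p = 0.0276) and DDIT3 (0.36, adjusted p = 0.0136) also rose. None of these passed edgeR's test with all 8 libraries, where FADS2 gave −0.59 (adjusted p = 0.234) and CTGF 0.64 (adjusted p = 0.295). DESeq2 called each of them on all 8 libraries, with adjusted p from 2.8e-05 for FADS2 to 0.0499 for DDIT3. The replicates of Enhancer-i cells without E2, which enter these fits, differed along GC content. After thinning, their difference had a rank correlation of 0.63 with it, against −0.07 and −0.08 in the control pairs without and with E2. Whether that trend had a part in these calls was not tested.

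The 61 genes that E2 raised lay slightly lower in Enhancer-i cells in both states. Their median Enhancer-i effect was −0.22 without E2, with 47 of 61 below 0, and −0.22 with E2, with 50 of 61 below 0. Fry's p-values were 0.00426 and 0.00218, and camera's with an estimated correlation were 0.00735 and 0.00339. Without the 4 site candidates among them the medians were −0.22 and −0.21, and without Enhancer-i replicate 2 with E2 they were −0.23 and −0.24 over all 61. The 24 genes that E2 lowered had medians of −0.04 and −0.09, with fry's p-values of 0.385 and 0.659. With all 8 libraries the shift was of similar size before and after E2, and the median difference of E2 effects over the risen genes was 0.02. As single libraries were left out, that difference ranged from −0.14 to 0.54 over the risen genes of each fit. Similar size is therefore not settled. A trend with GC content was not removed here.

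Whether chance could give as many genes was checked by dividing the 8 libraries into 4 and 4 in all 35 ways, in fits of 2 groups. For E2 averaged over the pools, 1 of the 35 splits, the real one, gave as many genes, 70 against at most 1 in any other split. This cannot exclude chance, since 1 of 35 is the smallest share such a check can give. The other splits also mix libraries with and without E2, which widens their spread and lowers their counts. For Enhancer-i averaged over E2 states, the real split gave 0 genes, so that 35 of 35 gave at least as many by construction and the count says nothing about chance. The highest of the other splits, 70, was the split by E2.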
